A study of Homo sapiens with 20 samples.

How the data were processed

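The deposited table of non-normalized values holds the intensity of each probe on each of the 20 arrays, as a mean bead signal that per the labels comes from biotin-labelled RNA on an Illumina BeadChip; the values show neither background subtraction nor scaling between arrays. Beside each intensity the authors deposited a detection p-value, which moves in steps of 1 in 770 and so was computed against negative control probes. The log2 values of the deposited series matrix were made by the authors with lumi per the labels (version, transform, normalization and filter not stated), and the values themselves show equal quartiles on every array. They hold 22579 probes. Each of their columns ranked its probes as its own array did, and no 2 arrays held identical values.

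The choices of normalization, filter, model, thresholds and gene lists, and the other settings to be tried, were made before the data were examined. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used. Intensities were background corrected with negative control information inferred from the detection p-values, quantile normalized and log2 transformed with limma's neqc (offset 16). Probes with a detection p under 0.01 on at least 3 arrays were kept (18269). Of these, 14194 are listed with 1 gene, and the probe with the highest mean stood for each of 10673 genes; probes are listed with a gene only within the authors' series matrix. Symbols were matched by Entrez ID to RefSeq, which changed 0 of them. Another 4075 detected probes have no single gene listed and were tested apart.

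Arrays with the same sample number in their titles were averaged, which left 14 samples from 20 arrays with 6 numbers held by 2 arrays. The residual correlation of such a pair had a median of -0.451, against -0.498 for other pairs of arrays in the same group, and -0.092 against -0.549 with the array set removed. Each such pair is divided between the 2 array sets, which were found from the number of detected probes after the data were seen. The labels give no replicate numbers that tie a treated sample to a control, and no paired analysis was possible because of this.

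A linear model with 6 group means was fitted in limma with empirical Bayes variances (8 residual and 5.09 prior degrees of freedom). Every p of a gene is from limma's moderated test, adjusted over all tested genes by Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. The contrasts were each retinoid against EtOH at each time and averaged over both times, ATRA against 9-cis RA in the same way, the change of each effect between the times, and EtOH at 48 against 24 h. Where a gene was detected on at most 2 of 4 or 1 of 3 arrays of a group, its fold is given as at least the ratio to the detection bound, with the undetected arrays set to that bound. Such a fold bounds only the ratio of the means of these samples and carries no sampling error, so it is no confidence limit. The p given beside it is that of the fitted difference, which uses the signals below detection. Of 36 fixed gene lists, 32 had at least 4 tested genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone use the members' own p-values only.

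Genes are named by a fixed rule. For a retinoid against EtOH these are the 10 highest and 10 lowest differences among passing genes in which all treated samples lie on one side of all controls. For other contrasts they are the passing genes with the 10 lowest p, or the 3 lowest where none passes. A fixed set of retinoid and pigment genes is always named, as are up to 4 members with the lowest p of each list that passed. The pipeline was run on simulated data with 200 changed genes among 10673. For ATRA at 24 h it recovered 22.4% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 98.5% of those changed 4-fold, with 2.5% false calls, and for the change of the ATRA effect between the times it recovered 1.49%, 40.3% and 92.4%. It called 0 of 30 random lists. The simulated values were drawn independently for each gene and sample, without array sets or correlation between genes. These rates therefore do not cover errors that such structure would cause in the real data.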

Results

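Gene expression was measured in Mel202, a human uveal melanoma cell line, exposed for 24 or 48 h to 100 nM all-trans retinoic acid (ATRA), to 100 nM 9-cis retinoic acid (9-cis RA) or to the ethanol vehicle (EtOH). The compounds are isomers that differ in the geometry of a double bond of the side chain. ATRA binds the retinoic acid receptors, and 9-cis RA binds these and also the retinoid X receptors. The series asks how retinoids regulate gene expression in uveal melanoma cells. It holds 20 Illumina BeadChips, with 3 arrays in each EtOH and 9-cis RA group and 4 in each ATRA group. Arrays that shared a sample number in their titles were averaged, which left 14 samples: 2 EtOH, 3 ATRA and 2 9-cis RA samples at each time. Samples are named here by the replicate numbers of their arrays, so that replicate 2-3 is the mean of arrays 2 and 3. The labels do not say whether the samples came from separate cultures, and the p-values measure only the spread between these samples, which may be technical.

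Between 26.5% and 36.2% of the probes were detected on an array. After the filter on detection 10673 genes were tested, and the number of arrays limits the precision. The arrays formed 2 sets by their number of detected probes, 12 arrays with 15870 to 17128 (set 1) and 8 arrays with 12561 to 14301 (set 2). Set 1 held 2 arrays of every group. Set 2 held 2 arrays of each ATRA group and 1 array of each other group, and replicate 4 of ATRA was measured in set 2 alone. Counts within set 2 compare single arrays of EtOH or 9-cis RA with a spread taken from the ATRA groups, so they say little about stability. The first principal component (42.7% of the variance) placed the EtOH samples between -41.14 and -18.98 and the retinoid samples between 0.08 and 25.90. The ends of the EtOH range were EtOH 48 h replicates 1 and 2-3, the only controls at 48 h. The EtOH 24 h samples lay at -31.58 and -33.81. On the second component (17.5%), ATRA 24 h replicate 4 (-23.95), both 9-cis RA 24 h samples (-16.62 and -17.94) and ATRA 48 h replicate 4 (-15.40) stood apart from the other 10 samples, which lay between -2.83 and 19.46.

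**Figure D1:**
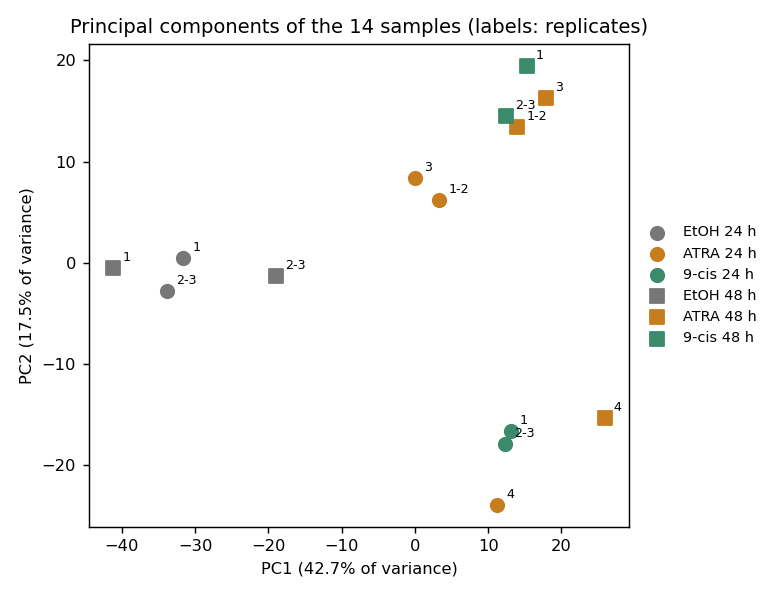
Scores of the 14 samples on the first (x axis, 42.7% of the variance) and second (y axis, 17.5%) principal components, 1 point per sample, coloured by group and labelled with replicate numbers. The 4 EtOH samples lie at -18.98 or below on the x axis, and 4 retinoid samples lie at -15.40 or below on the y axis.

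ATRA for 24 h raised genes of retinoid metabolism and of nuclear receptor signalling. CYP26A1, which encodes a retinoic acid hydroxylase, was not detected on any EtOH array and was at least 36.9-fold higher with ATRA (adjusted p = 2.63e-12; n = 3 ATRA and 2 EtOH samples, as in every comparison of ATRA with EtOH). Its 2 other detected probes gave smaller fitted differences in log2, 3.26 and 3.40 here and 3.10 to 4.51 in the other comparisons of a retinoid with EtOH at 1 time. LRAT, the enzyme that esterifies retinol, was at least 6.88-fold higher, and DHRS3, which reduces retinal to retinol, at least 1.44-fold higher (adjusted p = 1.96e-06 and 0.00272). RARB, a retinoic acid receptor, rose by 1.31 ± 0.15 (log2 difference ± SE, adjusted p = 0.000131). NRIP1, a corepressor of nuclear receptors, rose by 2.12 ± 0.17 (adjusted p = 4.38e-06), and CYP26B1, another retinoic acid hydroxylase, was at least 1.66-fold higher (adjusted p = 0.00153), detected on 1 of 3 EtOH arrays. RARA differed by 0.67 ± 0.25 (adjusted p = 0.139) and RXRA by -0.06 ± 0.15 (adjusted p = 0.855), neither past the threshold. CRABP2 and TGM2 did not pass the detection filter, and PLAAT4, DCT and STRA6 were not among the named probes, so these 5 genes were not analysed here.

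Other large rises at 24 h of ATRA were those of RASD1, a RAS-related G protein (3.62 ± 0.15), SPP1, which encodes osteopontin (3.24 ± 0.14), the salivary histatin HTN1 (2.91 ± 0.28) and FCRLA (2.80 ± 0.17), each with an adjusted p of 2.49e-05 or less. The salivary mucin MUC7, the anion exchanger SLC26A4, the lens crystallin CRYGC and UBAP1L were not detected with EtOH and were at least 4.91, 3.28, 3.12 and 4.02 times as high with ATRA (adjusted p of 1.28e-05 or less). Among the falls, SNORA12 changed by -2.20 ± 0.32 and RIMS2 of the presynaptic active zone by -2.15 ± 0.19. RALYL, the small heat shock protein gene HSPB7, SCRG1, OLFML2A and the growth factor gene FGF9 were detected on 1 or 2 of 4 ATRA arrays and were at least 5.40, 5.28, 3.70, 2.75 and 2.54-fold lower (adjusted p of 0.000982 or less for these 7 genes). SYBU and the neuronal adhesion gene NRCAM were not detected with ATRA and were at least 2.64-fold and 3.63-fold lower (adjusted p = 1.43e-07 and 1.96e-06). C1orf116, detected on 2 of 4 ATRA arrays, was at least 3.13-fold lower (adjusted p = 3.54e-05), while its other detected probe gave -0.37 in log2.

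Of 12 measured retinoic acid response genes, 7 were higher and 0 lower at 24 h of ATRA (9 and 0 adjusted over the list alone), with a median of 0.95, or 0.78 with undetected members at their bound. That median was 0.48 without background correction, 0.42 with the authors' series matrix values and 0.98 with equal array medians. The list passed camera's test (adjusted p = 6.18e-12) and also passed with an estimated correlation (adjusted p = 0.00241). The other 8 lists that passed with the preset correlation lost that call with an estimated one, and that p is given for each. Of 13 measured genes of retinoid metabolism and transport, 5 were higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.00125, and 0.117 with an estimated correlation). Among them were CYP26A1, LRAT, CYP26B1 and the retinaldehyde dehydrogenase ALDH1A2, at least 1.47-fold higher (0.34 in log2 from its other detected probe). Of 10 retinoid receptors and coregulators, 2 were higher, RARB and NRIP1 (2 adjusted over the list alone; adjusted p = 0.017, and 0.117 with an estimated correlation). Of 22 genes of melanocyte differentiation and pigmentation, 6 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00125, and 0.249 with an estimated correlation). RAB27A and MLPH, which move melanosomes, rose by 1.51 ± 0.16 and 0.81 ± 0.13, tyrosinase (TYR) by 0.75 ± 0.14 and the melanosomal transporter SLC45A2 by 0.57 ± 0.13. The 2 other detected probes of RAB27A gave 0.67 and 0.81. MITF, the melanocyte transcription factor, rose by 0.62 ± 0.15 (adjusted p = 0.0288), whereas its other detected probe gave -0.43. PMEL (-0.05 ± 0.13, adjusted p = 0.869) and MLANA (0.10 ± 0.15, adjusted p = 0.736) did not pass.

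Of 8 measured markers of the retinal pigment epithelium, another pigmented cell type of the eye, 3 were higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.000488, and 0.117 with an estimated correlation). These were MERTK, a receptor for phagocytosis of photoreceptor outer segments (1.90 ± 0.14), the potassium channel KCNJ13 (at least 2.30-fold) and LRAT, while RLBP1, not detected with EtOH and at least 1.02-fold higher, did not pass (adjusted p = 0.0889). LRAT also counts among the genes of retinoid metabolism and transport, so the lists share members and are not independent. Of 13 YAP and TEAD targets 0 were higher and 4 lower (0 and 5 adjusted over the list alone; adjusted p = 0.017, and 0.117 with an estimated correlation). FOXF2 lay at -1.82 ± 0.13 and FJX1 at -0.51 ± 0.14, WWC1 was at least 1.38-fold lower, and ARHGEF17 was not detected with ATRA and too low with EtOH for a fold. Of 18 genes of MAPK pathway output 4 were higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0131, and 0.201 with an estimated correlation). These were IER3 (2.06 ± 0.17), PHLDA1 (1.10 ± 0.18), ETV5 (0.68 ± 0.17) and SPRED1 (0.52 ± 0.14). Of the 5 genes in the list for class 2 uveal melanoma, the class with the higher risk of metastasis, 0 were higher and 2 lower (0 and 2 adjusted over the list alone; adjusted p = 0.0432, and 0.201 with an estimated correlation). Whether every member, PRAME included, marks that class was not tested. HTR2B, a serotonin receptor, changed by -1.18 ± 0.13 and RAB31 by -0.57 ± 0.14, while PRAME (-0.19 ± 0.17) and ECM1 (0.01 ± 0.12) did not pass. Of 4 measured Schwann and glial genes 1 was higher and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.0206, and 0.117 with an estimated correlation). The myelin gene MAG was at least 2.48-fold higher, and MBP gave 0.71 ± 0.20 (adjusted p = 0.0521, with 1.35 and 1.64 from its 2 other detected probes).

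In all, 614 of 10673 genes differed after 24 h of ATRA, 351 higher and 263 lower, 204 of them by 2-fold or more. The 2-fold count depends on the scaling. Passing rises over 2-fold numbered 122, but 64 without background correction, 49 with the authors' series matrix values and 132 with equal array medians. Within array set 1 alone 477 genes passed and within set 2 alone 87, and 844 passed with the array set as a term and the sample number as a random block. With that term the class 2 list no longer passed (adjusted p = 0.0611, with a median of -0.19 before and -0.17 after), nor did FJX1 (-0.51 ± 0.14 before and -0.47 ± 0.16 after, adjusted p = 0.0864). The calls of ARHGEF17 (fitted values -0.58 ± 0.15 and -0.57 ± 0.17, adjusted p = 0.0516) and WWC1 (fitted values -0.69 ± 0.17 and -0.58 ± 0.20, adjusted p = 0.0856) also ended. In these 3 genes the SE grew, and the size fell by less than 1 SE. RARA (0.72 ± 0.20, adjusted p = 0.0274) and MBP (0.72 ± 0.18, adjusted p = 0.0137) passed with it. With the samples apart on the second component as a term RARA (0.89 ± 0.17, adjusted p = 0.00643) and RLBP1 (adjusted p = 0.0491) passed, and the class 2 list did not (median -0.06, adjusted p = 0.0591). The count was 211 without EtOH 24 h replicate 1, 218 without EtOH 24 h replicate 2-3 and 387 without ATRA 24 h replicate 1-2. It was 1082 without either EtOH 48 h sample (which enter only the shared estimate of the spread), 399 without the 4 samples apart on the second component and 1593 with the 20 arrays taken as independent.

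**Figure D2:**
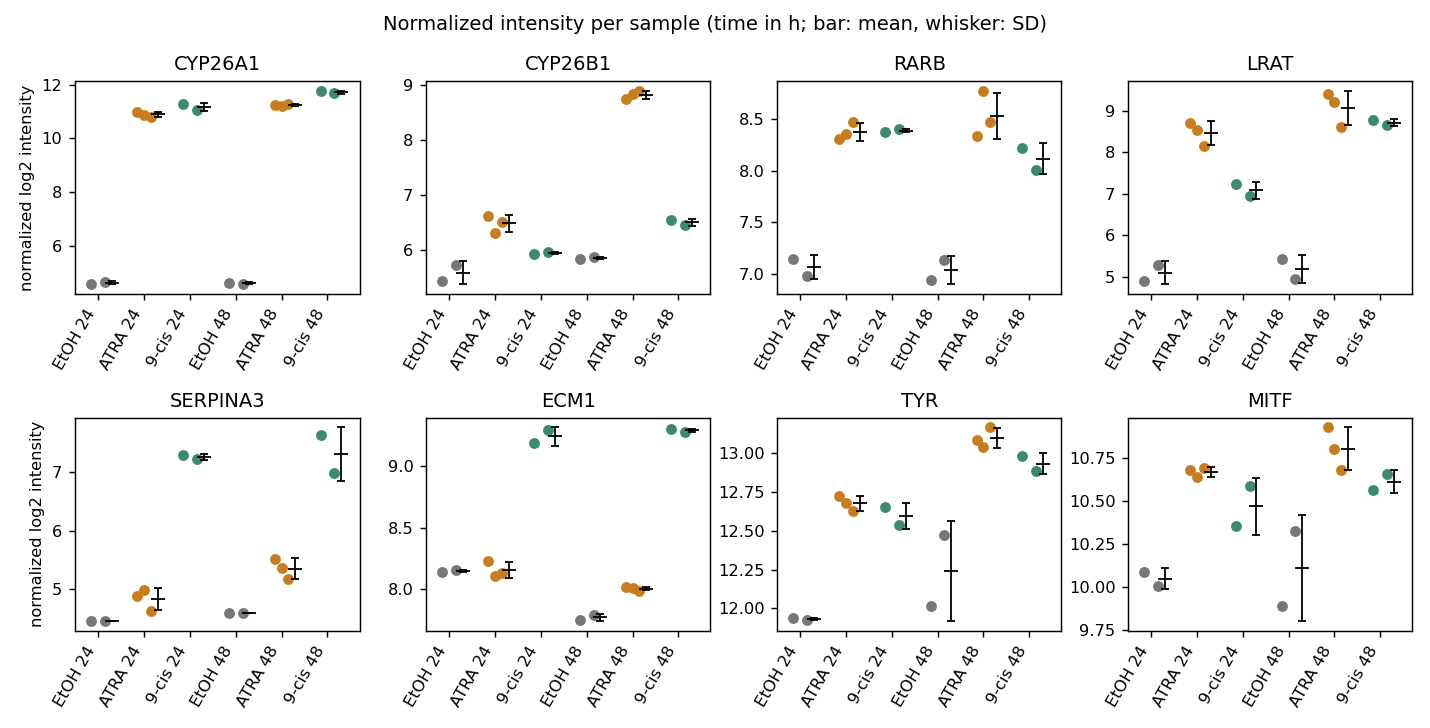
Normalised log2 intensity (y axis) of 8 named genes in the 14 samples, 1 point per sample, by group (x axis), with a bar at each group's mean and a whisker of 1 SD. CYP26A1 is high in every retinoid sample, and CYP26B1 is highest after 48 h of ATRA.

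After 48 h of ATRA the same retinoid-handling genes stood higher than in EtOH. CYP26A1 was at least 46.7-fold higher (adjusted p = 1.27e-12), LRAT at least 10.4-fold and DHRS3 at least 2.25-fold, while CYP26B1 rose by 2.97 ± 0.14 (adjusted p = 2.22e-08). RARB rose by 1.49 ± 0.15 (0.79 and 2.00 from its other detected probes), NRIP1 by 2.60 ± 0.17 and RARA by 0.91 ± 0.25 (adjusted p = 0.0227), while RXRA gave 0.03 ± 0.15 (adjusted p = 0.911). HTN1 (4.26 ± 0.28), SPP1 (3.66 ± 0.14), RASD1 (3.47 ± 0.15) and the lipid raft gene RFTN1 (3.33 ± 0.15) rose, with adjusted p of 5.12e-07 or less. MUC7, SLC26A4, EGFL8 and the membrane peptidase MME were at least 18.0, 8.39, 7.09 and 5.64 times as high as in EtOH, where they were not detected. The matricellular gene CCN3 changed by -2.32 ± 0.20. RALYL, the cadherin CDH7, OLFML2A, LFNG, which glycosylates Notch, and the collagen COL9A1 were detected on 1 or 2 of 4 ATRA arrays and were at least 6.42, 3.72, 3.29, 3.16 and 2.91-fold lower (adjusted p of 0.00017 or less for these 6 genes). HSPB7, SNORA12, FGF9 and SYBU were not detected with ATRA and were at least 5.20, 3.50, 3.36 and 2.46-fold lower.

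Of the 12 retinoic acid response genes 8 were higher and 0 lower at 48 h (8 and 0 adjusted over the list alone; median 1.35, or 1.18 with undetected members at their bound; adjusted p = 1.19e-08, and 0.00735 with an estimated correlation). That median was 0.89 without background correction, 0.79 with the authors' series matrix values and 1.37 with equal array medians. Of the 22 melanocyte genes 11 were higher and 1 lower (12 and 3 adjusted over the list alone; adjusted p = 0.000993, and 0.302 with an estimated correlation). Among them were RAB27A (1.38 ± 0.16, with 0.33 and 0.30 from its other detected probes), the endothelin receptor EDNRB (1.15 ± 0.17, with 1.82 and 1.37 from its other detected probes), TYR (0.86 ± 0.14), MLPH (0.78 ± 0.13) and MITF (0.69 ± 0.15, adjusted p = 0.00754, with 0.12 from its other probe). PMEL (0.01 ± 0.13) and MLANA (0.31 ± 0.15, adjusted p = 0.173) did not pass. Of the 8 pigment epithelium markers 5 were higher and 0 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00275, and 0.161 with an estimated correlation). MERTK lay at 2.29 ± 0.14, and KCNJ13 and RLBP1, a retinaldehyde carrier, were at least 5.33-fold and 1.41-fold higher. Retinoid metabolism and transport had 6 higher and 3 lower of 13 (the counts adjusted over the list alone were equal; adjusted p = 0.013, and 0.228 with an estimated correlation). ALDH1A2 rose by 1.40 ± 0.12, with 0.77 from its other detected probe. Of the 10 receptors and coregulators 5 were higher and 0 lower (5 adjusted over the list alone; adjusted p = 0.0079, and 0.161 with an estimated correlation). Among them were RXRB (0.66 ± 0.14) and NCOA1 (0.59 ± 0.14), whose other detected probe gave -0.14. Of the 13 YAP and TEAD targets 0 were higher and 4 lower (0 and 5 adjusted over the list alone; adjusted p = 0.0335, and 0.161 with an estimated correlation). FOXF2 changed by -1.82 ± 0.13 and FJX1 by -0.75 ± 0.14, and GADD45B and ARHGEF17 were at least 1.48-fold and 1.12-fold lower.

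In total 1856 genes differed at 48 h of ATRA, 919 higher and 937 lower, 469 by 2-fold or more. Passing rises over 2-fold numbered 241, but 104 without background correction, 89 with the authors' series matrix values and 263 with equal array medians. Set 1 alone gave 1511 genes, set 2 alone 101, and the fit with the array set as a term and the sample number as a block gave 2139. In that fit the YAP and TEAD list no longer passed (adjusted p = 0.0785, with a median of -0.31 before and -0.38 after), nor did GADD45B (adjusted p = 0.0641), whose fitted value of -0.65 ± 0.19 became -0.62 ± 0.23, so that the SE grew more than the size fell. The median of the YAP and TEAD list was smaller under other scalings, at -0.14 without background correction, -0.16 with equal array medians and -0.098 with the authors' series matrix values. Without EtOH 48 h replicate 2-3, 2 lists passed in place of 6. The count of genes was 816 without EtOH 48 h replicate 1, 3273 without EtOH 48 h replicate 2-3 and 583 in a fit of these 2 groups alone.

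9-cis RA for 24 h raised many of the genes that ATRA raised. CYP26A1 was at least 45.0-fold higher than with EtOH (adjusted p = 4.82e-12; n = 2 samples in each group, as in every comparison of 9-cis RA with EtOH), LRAT at least 2.64-fold and DHRS3 at least 1.77-fold. RARB rose by 1.32 ± 0.17 (adjusted p = 0.000245) and NRIP1 by 1.90 ± 0.18, while CYP26B1 (at least 1.14-fold, adjusted p = 0.128), RARA (0.39 ± 0.27, adjusted p = 0.341) and RXRA (-0.07 ± 0.17, adjusted p = 0.821) did not pass. RASD1 (4.14 ± 0.16), SPP1 (3.35 ± 0.16), HTN1 (3.28 ± 0.31), FCRLA (3.10 ± 0.19) and the homeobox gene MSX1 (2.75 ± 0.14) rose. SLC26A4, MUC7, CRYGC and the protease inhibitor SERPINA3 were not detected with EtOH and were at least 6.45, 4.53, 4.41 and 2.97 times as high. Among the falls were RALYL (-3.02 ± 0.27), the bHLH factor MSC (-2.68 ± 0.30), SNORA12 (-2.38 ± 0.35), FOXF2 (-2.35 ± 0.14), SERPINI1 (-2.31 ± 0.23, with -1.50 from its other detected probe) and NACC1 (-2.27 ± 0.53, with -1.105 from its other detected probe). HSPB7, the glutathione transferase GSTA2 and OAZ3 were detected on 1 of 3 9-cis RA arrays and were at least 6.88, 6.82 and 3.68-fold lower (adjusted p of 0.0154 or less for these 9 genes). SYBU was at least 3.32-fold lower.

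Of the 12 retinoic acid response genes 7 were higher and 0 lower (8 and 1 adjusted over the list alone; median 0.80, or 0.75 with undetected members at their bound; adjusted p = 5.34e-06, and 0.0242 with an estimated correlation). That median was 0.58 without background correction, 0.46 with the authors' series matrix values and 0.76 with equal array medians. Of the 8 pigment epithelium markers 4 were higher and 0 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0372, and 0.356 with an estimated correlation). MERTK rose by 2.48 ± 0.15, and KCNJ13 and RLBP1 were at least 2.05-fold and 1.43-fold higher. Of the 22 melanocyte genes 5 were higher and 2 lower (9 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.18, and 0.656 with an estimated correlation). TYR rose by 0.66 ± 0.16 (adjusted p = 0.0155), and MITF (0.42 ± 0.17, adjusted p = 0.0978, with -0.57 from its other detected probe), PMEL (-0.14 ± 0.14) and MLANA (-0.04 ± 0.16) did not pass.

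At 24 h 9-cis RA changed 1546 genes, 929 higher and 617 lower, 467 by 2-fold or more. Passing rises over 2-fold numbered 289, but 96 without background correction, 71 with the authors' series matrix values and 290 with equal array medians. Both 9-cis RA 24 h samples stood apart on the second principal component together with replicate 4 of ATRA at each time. NACC1 followed these 4 samples, at log2 intensities of 6.54 to 7.21 in them and 8.29 or more in the other 10. With the samples apart as a fixed term 523 genes passed, 400 of them shared with the 1546. NACC1 (-0.68 ± 0.22, adjusted p = 0.103) and TYR (0.65 ± 0.20, against 0.66 ± 0.16 before, adjusted p = 0.0879) no longer passed, whereas RARA passed (1.03 ± 0.23, adjusted p = 0.0243). The calls of GSTA2 (fitted values -3.32 ± 0.65 before and -2.62 ± 0.84 after, adjusted p = 0.0994) and OAZ3 (fitted values -2.42 ± 0.54 and -1.98 ± 0.71, adjusted p = 0.137) also ended. The size of NACC1 fell by most of its value, while those of GSTA2, OAZ3 and TYR fell by less than their SE in that fit, which was larger than before. Set 1 alone gave 2234 genes, set 2 (1 array against 1) 49, and the fit with the array set as a term and the sample number as a block 2182. The pigment epithelium list had an adjusted p of 0.0361 in that fit and of 0.052 within set 1 (median 0.76 before, 0.76 in that fit and 0.80 within set 1). In place of 2 lists 1 passed without either EtOH 48 h sample or ATRA 48 h replicate 3, and 4 without EtOH 24 h replicate 2-3, and 10 passed with the samples apart as a term. The count of genes was 464 without EtOH 24 h replicate 1, 343 without EtOH 24 h replicate 2-3, 301 without 9-cis RA 24 h replicate 1 and 522 without 9-cis RA 24 h replicate 2-3. It was 3927 in a fit of these 2 groups alone and 3305 with the 20 arrays as independent samples.

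**Figure D3:**
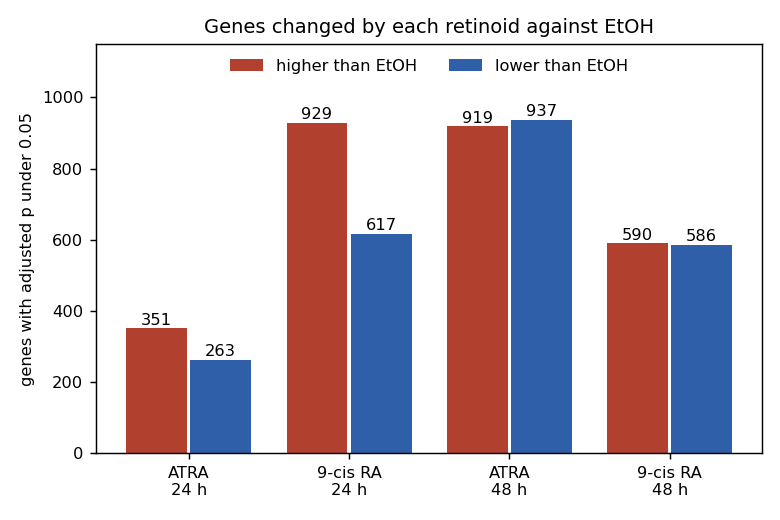
Number of genes (y axis) with an adjusted p under 0.05 against EtOH, higher (red bars) and lower (blue bars), for each retinoid and time (x axis), of 10673 tested. The counts run from 351 higher and 263 lower (ATRA 24 h) to 919 higher and 937 lower (ATRA 48 h).

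After 48 h of 9-cis RA, CYP26A1 was at least 65.1-fold higher than with EtOH (adjusted p = 1.68e-12), MUC7 at least 21.9-fold and SLC26A4 at least 15.7-fold. LRAT was at least 8.11-fold higher, UBAP1L at least 5.91-fold and DHRS3 at least 2.42-fold. HTN1 rose by 4.61 ± 0.31, RASD1 by 4.07 ± 0.16, SPP1 by 3.72 ± 0.16, RFTN1 by 3.55 ± 0.16 and the matrix gene MGP by 3.42 ± 0.18 (adjusted p of 7.86e-07 or less). NRIP1 rose by 2.23 ± 0.18, RARB by 1.08 ± 0.17 (adjusted p = 0.00105), RARA by 1.08 ± 0.27 (adjusted p = 0.0207) and CYP26B1 by 0.65 ± 0.15 (adjusted p = 0.0153), while RXRA gave -0.17 ± 0.17 (adjusted p = 0.576). RALYL changed by -3.01 ± 0.27, CCN3 by -2.56 ± 0.22, the scaffold gene AHNAK by -2.45 ± 0.19 and CDH7 by -2.23 ± 0.30. HSPB7, SNORA12, FGF9, OLFML2A, SYBU and ISM1 were not detected with 9-cis RA and were at least 5.51, 3.71, 3.56, 3.51, 2.61 and 2.39-fold lower (adjusted p of 0.00124 or less).

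The 12 retinoic acid response genes again had 8 higher and 0 lower (8 and 1 adjusted over the list alone; median 1.08, also with undetected members at their bound; adjusted p = 3.95e-08, and 0.00906 with an estimated correlation). That median was 0.72 without background correction, 0.53 with the authors' series matrix values and 1.09 with equal array medians. Of the 22 melanocyte genes 6 were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.00672, and 0.352 with an estimated correlation). RAB27A lay at 1.25 ± 0.17 (0.86 and 0.67 from its other detected probes), EDNRB at 1.23 ± 0.19, TYR at 0.69 ± 0.16, SLC45A2 at 0.63 ± 0.14 (0.45, 0.23 and 0.75 from its other detected probes) and the melanocortin receptor MC1R at -0.71 ± 0.16. MITF (0.50 ± 0.17, adjusted p = 0.0699), PMEL (0.06 ± 0.14) and MLANA (0.31 ± 0.16) did not pass. Of the 8 pigment epithelium markers 4 were higher and 0 lower (4 and 2 adjusted over the list alone; adjusted p = 0.00326, and 0.144 with an estimated correlation). MERTK rose by 2.45 ± 0.15, and KCNJ13 and RLBP1 were at least 6.10-fold and 1.85-fold higher. Of 12 measured LXR targets, genes of cholesterol and lipid handling, 4 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.035, and 0.144 with an estimated correlation). ABCA1, a cholesterol exporter, rose by 1.37 ± 0.19, APOC1 by 0.84 ± 0.22 and the desaturase SCD by 0.60 ± 0.17, and PLTP changed by -1.02 ± 0.17, with -0.27 from its other detected probe. Retinoid metabolism and transport had 5 higher and 2 lower of 13 (8 and 3 adjusted over the list alone; adjusted p = 0.00326, and 0.144 with an estimated correlation). ALDH1A2 rose by 1.35 ± 0.14, with 0.94 from its other detected probe. The receptors and coregulators had 3 higher and 0 lower of 10 (4 and 0 adjusted over the list alone; adjusted p = 0.0348, and 0.144 with an estimated correlation). The YAP and TEAD targets had 0 higher and 3 lower of 13 (0 and 3 adjusted over the list alone; adjusted p = 0.031, and 0.144 with an estimated correlation). FOXF2 lay at -2.10 ± 0.14 and FJX1 at -0.89 ± 0.15.

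At 48 h 9-cis RA changed 1176 genes, 590 higher and 586 lower, 413 by 2-fold or more. Passing rises over 2-fold numbered 233, but 112 without background correction, 86 with the authors' series matrix values and 250 with equal array medians. Set 1 alone gave 1432 genes, set 2 alone 73, and the fit with the array set as a term and the sample number as a block 1478. All 7 lists still passed in that fit, and NCOA1 passed in it (0.42 ± 0.14, adjusted p = 0.046, against 0.44 ± 0.15 and 0.0869 without the term). MITF passed with the samples apart as a term (0.50 ± 0.16, adjusted p = 0.0486). Without EtOH 48 h replicate 2-3, 3 lists passed in place of 7. The count of genes was 699 without EtOH 48 h replicate 1, 2576 without EtOH 48 h replicate 2-3, 442 without 9-cis RA 48 h replicate 1 and 583 without 9-cis RA 48 h replicate 2-3. It was 248 in a fit of these 2 groups alone and 1974 with the 20 arrays as independent samples.

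**Figure D4:**
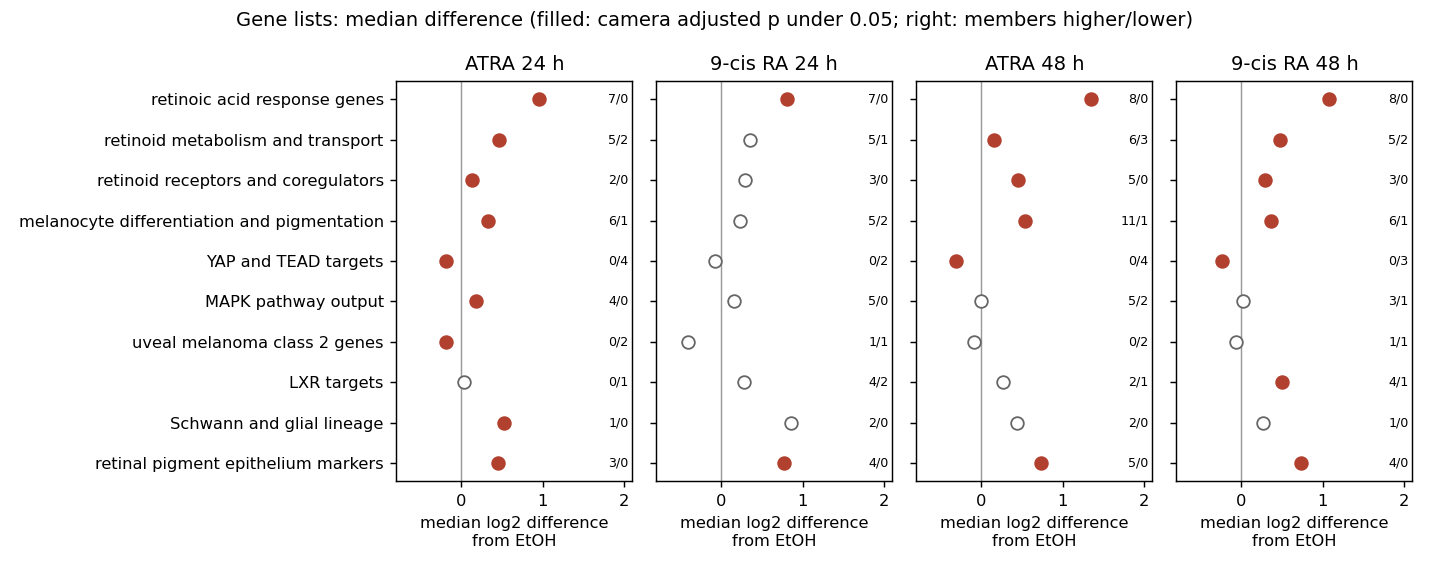
Median log2 difference from EtOH (x axis) of the measured members of 10 gene lists (y axis) for each retinoid and time, filled where camera's adjusted p was under 0.05, with the numbers of members higher and lower at the right of each panel. The retinoic acid response genes lie between 0.80 and 1.35 in the 4 panels.

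The fits averaged over both times called 2890 genes with ATRA (1425 higher and 1465 lower) and 2524 with 9-cis RA (1357 higher and 1167 lower). Set 1 alone gave 2284 and 3012, and set 2 alone 396 and 225. Without EtOH 24 h replicate 1 or 2-3 ATRA gave 1850 and 1697 genes, and 9-cis RA gave 1480 without EtOH 24 h replicate 2-3, 1529 without 9-cis RA 24 h replicate 1 and 1488 without 9-cis RA 48 h replicate 1. The calls of the isomers overlapped. At 24 h 310 genes were higher and 194 lower with both and 1 gene moved in opposite directions. At 48 h 507 were higher and 486 lower with both and 0 moved in opposite directions. Independent lists of these sizes would share 30.6 higher and 15.2 lower genes at 24 h and 50.8 and 51.4 at 48 h. Across genes, which are not independent replicates, the differences from EtOH of the isomers correlated at r = 0.859 at 24 h and 0.896 at 48 h, where unchanged groups against the same controls gave 0.548 and 0.549 in simulation, with an overlap of 0 genes by limma. The covariance was 0.175 against 0.0300 simulated at 24 h and 0.218 against 0.0301 at 48 h. The 2 EtOH samples of a time cannot be divided into groups of 2, and part of the excess may come from the shared controls. Over the 4 comparisons with EtOH 2777 genes were called in any and 372 in all 4, 222 of them higher and 150 lower.

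In the direct comparison of the isomers at the same dose and time, few genes passed. At an unadjusted p under 0.05 by limma, 1114 of 10673 genes differed at 24 h and 567 at 48 h. In the simulated data the comparison at 24 h recovered 23.9% of genes changed 1.5-fold and 64.2% of those changed 2-fold. Smaller differences may therefore have been missed. At 24 h SERPINA3, an acute-phase protease inhibitor, was at least 2.54-fold lower with ATRA than with 9-cis RA (adjusted p = 7.07e-05; n = 3 ATRA and 2 9-cis RA samples, as at 48 h). The matrix gene ECM1 differed by -1.08 ± 0.12 (ATRA minus 9-cis RA, adjusted p = 0.00177), the cholesterol exporter ABCA1 by -1.11 ± 0.17 (0.0434) and KIAA1217 by -0.95 ± 0.15 (0.0446). PHLDA2, detected on 1 of 4 ATRA arrays, was at least 1.65-fold lower (0.0434). The adhesion receptor ADGRG1 and DNM3 were at least 1.31-fold and 1.05-fold lower with ATRA (0.0418 and 0.0169). At 48 h SERPINA3 (at least 2.73-fold, adjusted p = 0.000304), ECM1 (-1.28 ± 0.12, 0.000243) and IL1RAPL1 (-0.94 ± 0.14, 0.0472) were lower with ATRA, and CYP26B1 was higher by 2.32 ± 0.14 (3.66e-06). Averaged over both times 23 genes differed, 3 higher and 20 lower with ATRA, among them ECM1 (-1.19 ± 0.08), SLC26A4 (-0.94 ± 0.12) and CYP26B1 (1.43 ± 0.10), with adjusted p of 0.0198 or less. The other detected probe of ECM1 gave -0.35 at 24 h, -1.39 at 48 h and -0.87 over both. SERPINA3 (adjusted p = 3.35e-06), ETNPPL (0.00935), DNM3 (0.00935), IL1RAPL1 (0.0116), ARHGDIB (0.0161), ADGRG1 (0.0164) and PHLDA2 (0.0198) were also lower. No size is given for their means, because each was detected on at most 2 of 4 ATRA arrays at 1 time or both. At 48 h DNM3 was detected with neither isomer, and PHLDA2 on 1 of 4 ATRA and 1 of 3 9-cis RA arrays. DNM3, PHLDA2 and ADGRG1 passed at 24 h but had an adjusted p of 0.877 at 48 h, so their calls over both times rest mostly on 24 h.

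Of the 1655 genes called with either isomer at 24 h, 1425 (86.1%) had a 95% interval of the difference between the isomers that lay within 1 log2 unit of 0, and at 48 h this held for 1962 of 2039 (96.2%). Within 0.5 log2 units of 0 lay the intervals of 327 (19.8%) and 759 (37.2%). At 24 h 0 of 32 gene lists differed between the isomers by camera with the preset or an estimated correlation (4 and 1 at an unadjusted p under 0.05), and fry called 3. At 48 h the class 2 list was lower with ATRA than with 9-cis RA (0 higher and 1 lower of 5, also adjusted over the list alone; adjusted p = 0.0389, and 0.296 with an estimated correlation). The member that passed was ECM1, and HTR2B (-0.25 ± 0.13), RAB31 (-0.16 ± 0.14) and CDH1 (0.25 ± 0.16) did not pass. Against EtOH, ECM1 gave 0.01 ± 0.12 and 0.23 ± 0.12 with ATRA at 24 and 48 h, neither past the threshold. With 9-cis RA it rose by 1.09 ± 0.13 and 1.52 ± 0.13 (adjusted p = 0.000126 and 5.11e-06). The hypoxia and glycolysis genes were higher with ATRA as a list, with 0 of 26 members past the threshold over all genes or adjusted over the list alone (adjusted p = 0.0389, and 0.296 with an estimated correlation). The glucose transporter SLC2A1 gave 0.74 ± 0.27, hexokinase HK2 0.55 ± 0.18 (-0.04 from its other detected probe), P4HA1 0.49 ± 0.20 and NDRG1 0.44 ± 0.19. Averaged over both times the class 2 list (0 higher and 1 lower; adjusted p = 0.00933, and 0.19 with an estimated correlation), the melanocyte list (0 of 22 past the threshold, 1 higher adjusted over the list alone; adjusted p = 0.00933, and 0.327 with an estimated correlation) and the retinoic acid response list (1 higher and 0 lower, 2 and 1 adjusted over the list alone; adjusted p = 0.0295, and 0.19 with an estimated correlation) differed, the class 2 list being lower with ATRA and the others higher. Named members of these lists that did not pass were OCA2 (0.37 ± 0.09), SLC24A5 (0.29 ± 0.10), GPR143 (0.28 ± 0.12), MLPH (0.23 ± 0.10), LRAT (0.87 ± 0.17, adjusted p = 0.0677), NRIP1 (0.30 ± 0.12) and CYP26A1 (-0.38 ± 0.09, adjusted p = 0.16). Of the 2 lists at 48 h 0 passed without ATRA 24 h replicate 4, ATRA 48 h replicate 3 or 9-cis RA 48 h replicate 2-3, and 7 without ATRA 48 h replicate 4. Also, 1 passed without either EtOH sample of either time, ATRA 24 h replicate 3, ATRA 48 h replicate 1-2 or 9-cis RA 48 h replicate 1. Of the 3 over both times 1 passed without 9-cis RA 24 h replicate 2-3, ATRA 48 h replicate 4 or 9-cis RA 48 h replicate 2-3, and 7 without 9-cis RA 24 h replicate 1.

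The counts of genes that differed between the isomers were 7 at 24 h (7 lower with ATRA), 4 at 48 h and 23 over both times. Set 1 alone, in which ATRA 24 h lacks replicate 4, gave 363, 1 and 33 genes, and set 2 alone 0, 0 and 1 (223 and 295 genes at an unadjusted p under 0.05 by limma at 24 and 48 h). The fit with the array set as a term and the sample number as a block gave 12, 6 and 26. In that fit KIAA1217 at 24 h (-0.95 ± 0.15 before and -0.86 ± 0.23 after, adjusted p = 0.177) and IL1RAPL1 at 48 h (-0.94 ± 0.14 and -0.88 ± 0.19, 0.175) no longer passed. The calls of DNM3 at 24 h (fitted values -1.10 ± 0.15 and -0.99 ± 0.20, 0.0844) and over both times (-0.77 ± 0.11 and -0.66 ± 0.14, 0.0642) and of ARHGDIB over both times (-0.77 ± 0.11 and -0.65 ± 0.15, 0.0721) ended as well, each with a larger SE and most of its size kept. The class 2 list at 48 h no longer passed (median -0.16 before and -0.12 after, adjusted p = 0.0679). LRAT passed over both times in that fit (0.97 ± 0.14, adjusted p = 0.00322) and with the samples apart as a term (0.78 ± 0.12, adjusted p = 0.0208). The 3 lists over both times did not pass within either set alone (adjusted p of 0.0837 or more). With the samples apart on the second component as a term 3, 5 and 44 genes passed. With that term ABCA1 (-0.95 ± 0.18, adjusted p = 0.136) and KIAA1217 (-0.91 ± 0.17, 0.136) at 24 h and IL1RAPL1 (-0.92 ± 0.14, 0.0559) at 48 h no longer passed. ADGRG1 (fitted values -1.12 ± 0.17 before and -1.15 ± 0.20 after, 0.114) and PHLDA2 (fitted values -1.44 ± 0.23 and -1.62 ± 0.25, 0.0815) at 24 h did not pass either. None of these 5 sizes moved by more than 1 SE. The melanocyte list over both times no longer passed (median 0.06 before and 0.03 after, adjusted p = 0.0541), and 1 list passed at 24 h and 6 at 48 h. At 24 h the count fell to 1 without 9-cis RA 24 h replicate 2-3, 2 without 9-cis RA 24 h replicate 1 or ATRA 24 h replicate 1-2, and 3 without ATRA 24 h replicate 4, ATRA 48 h replicate 1-2 or 3, or either EtOH 24 h sample, and was 12 without ATRA 48 h replicate 4. Over both times it was 4 and 6 without 9-cis RA 24 h replicate 1 and replicate 2-3, 5 without either 9-cis RA 48 h sample, 8 and 11 without ATRA 24 h replicate 1-2 and replicate 3, 9 without ATRA 48 h replicate 1-2, 15 without either EtOH 24 h sample and 40 without either EtOH 48 h sample.

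**Figure D5:**
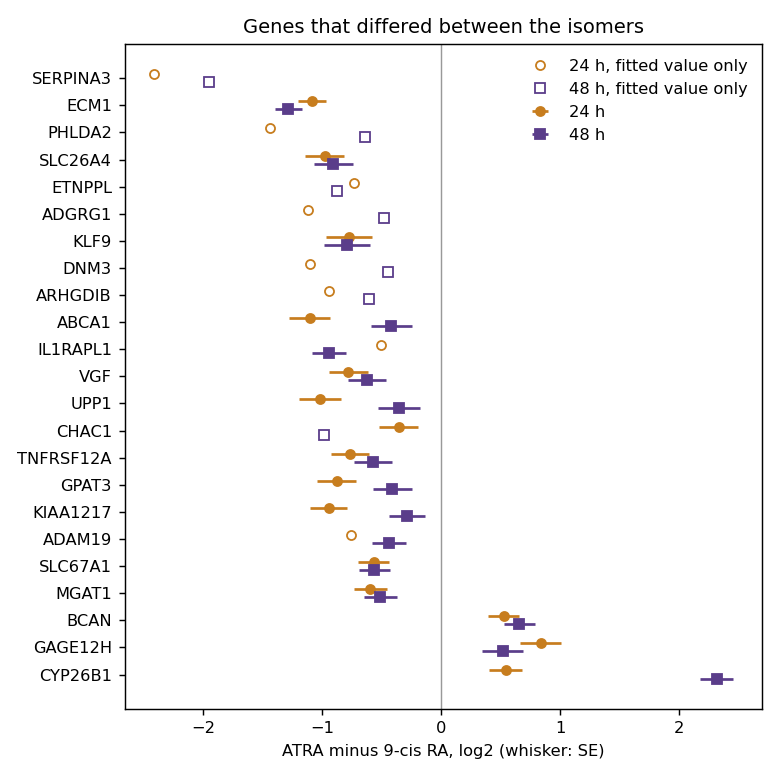
Difference between ATRA and 9-cis RA (x axis, log2, with SE as whiskers) of the genes that differed between the isomers averaged over both times (y axis), at 24 h and at 48 h, with open symbols for fitted values where ATRA was detected on at most 2 of 4 arrays or 9-cis RA on at most 1 of 3. ECM1 lies at -1.08 and -1.28 and CYP26B1 at 0.54 and 2.32.

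The response to ATRA differed between the times in 4 genes, CYP26B1, MXD4, DCN and KCNJ13. The effect on CYP26B1 (adjusted p = 0.00101) was at least 1.66-fold at 24 h and 2.97 ± 0.14 in log2 at 48 h, and its mean log2 intensity with ATRA was 6.49 and 8.83. That on MXD4, a MAX-binding repressor, was 0.03 ± 0.12 and 1.27 ± 0.12 (difference 1.24 ± 0.17, adjusted p = 0.0289). DCN, the proteoglycan decorin, passed as well (adjusted p = 0.0411) but was detected on 0 arrays of EtOH and of ATRA at 24 h and on all 4 of ATRA at 48 h. KCNJ13 passed with ATRA (adjusted p = 0.0289) and as the 1 gene with 9-cis RA (adjusted p = 0.0179). It was not detected on any EtOH array, and its mean log2 intensity at 24 and 48 h was 6.89 and 8.11 with ATRA and 6.72 and 8.30 with 9-cis RA. No size of the difference between the times is given for CYP26B1, DCN and KCNJ13, since it would rest in part on signals below detection. As lists, the ATRA effect at 48 h was higher for the retinoic acid response genes (1 member higher, also adjusted over the list alone; adjusted p = 0.0194), the pigment epithelium markers (1 member higher, also adjusted over the list alone; 0.0341) and the PPAR targets and fatty acid oxidation genes (0 members past the threshold, also adjusted over the list alone; 0.0341). It was lower for S phase and DNA replication (0 members, also adjusted over the list alone; 0.0194), MAPK pathway output (0 members, 2 lower adjusted over the list alone; 0.0341) and the unfolded protein response (0 members, also adjusted over the list alone; 0.0341). With an estimated correlation the adjusted p of these lists was 0.246, and 0.402 for the unfolded protein response, so none passed. The median of the MAPK list was -0.23 for this change of the ATRA effect and 0.23 for EtOH at 48 against 24 h. A change in the EtOH controls therefore enters its lower ATRA effect. Of the 6 lists 0 passed without EtOH 24 h replicate 2-3 or EtOH 48 h replicate 2-3, and 3 without replicate 1-2 or 4 of ATRA at either time. Named members below the threshold were CD36 (0.62 ± 0.22), SLC25A20 (0.63 ± 0.22, with 1.197 from its other detected probe), HADHB (0.37 ± 0.19), PLIN2 (0.35 ± 0.18, with 0.08 from its other detected probe), the replication gene MCM4 (-0.46 ± 0.19), the immediate early gene EGR1 (-0.98 ± 0.23, adjusted p = 0.448), ETV4 (-0.85 ± 0.23) and CHAC1 (adjusted p = 0.996). For 9-cis RA 0 of 32 lists differed by camera (6 at an unadjusted p under 0.05), and fry called 4.

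Without a retinoid, 3 genes differed between 48 and 24 h of EtOH. The cadherin CDH1 rose by 1.28 ± 0.18 (adjusted p = 0.0245), MGP changed by -1.33 ± 0.18 (adjusted p = 0.0201) and MYOT was at least 1.70-fold lower (adjusted p = 0.00675; n = 2 samples at each time). MAPK pathway output was higher at 48 h as a list, with 0 of 18 members past the threshold (2 higher adjusted over the list alone; adjusted p = 0.00669, and 0.318 with an estimated correlation), and EGR1 gave 0.69 ± 0.18 and IER3 0.66 ± 0.19. That list did not pass without EtOH 48 h replicate 2-3, and 2 lists passed without EtOH 48 h replicate 1. The counts for ATRA over time, 9-cis RA over time and EtOH were 3, 98 and 0 within set 1, 0, 0 and 0 within set 2 (439, 638 and 562 at an unadjusted p under 0.05 by limma, and 834 for EtOH in set 1). They were 11, 23 and 7 with the array set as a term and the sample number as a block. Without EtOH 48 h replicate 2-3 they were 75, 244 and 366. The ATRA count of 4 was 5 without EtOH 48 h replicate 1 or ATRA 24 h replicate 4, and 1 without any other single sample. The EtOH count was 9 without EtOH 48 h replicate 1, 1 without ATRA 24 h replicate 1-2 or either 9-cis RA 24 h sample and 0 without either EtOH 24 h sample. The 9-cis RA count was 4 without EtOH 48 h replicate 1 or ATRA 48 h replicate 4, 2 without ATRA 24 h replicate 1-2, and 0 without either EtOH 24 h sample, any 9-cis RA sample or ATRA 48 h replicate 1-2.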

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

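The tests on the samples apart, on the array sets and on the strength of the response were chosen after the data were seen, and the tests of LXR targets, PPAR targets and other groupings of the samples before.

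9-cis RA at 24 h changed 1546 genes and ATRA 614, although a direct comparison of the compounds called 7. Of the 1041 genes called with 9-cis RA and not with ATRA at 24 h, 83.0% differed between 9-cis RA 24 h and ATRA 24 h replicates 1 to 3 in the direction in which ATRA 48 h replicate 4 differed from the other ATRA 48 h samples. The principal components had already placed these samples together and the share over all genes was 72.5%, so a high share was fixed beforehand and decides nothing. Whether an expression difference that runs across the treatments adds to the 9-cis RA count stays open. Of the genes called at 24 h, 36.5% were also called at 48 h with 9-cis RA and 83.7% with ATRA. Their sign was the same at 48 h in 87.8% and 98.9%. Across genes the effects at the 2 times correlated at r = 0.599 and 0.811. At an unadjusted p under 0.05 by limma, the effect differed between the times in 1433 and 499 genes. These values cannot tell such a difference from a response that changes with time. With the samples apart as a term 523 genes passed (median size of the 1546 effects 0.82 before and 0.61 after in log2, with median SE 0.190 and 0.212). A stronger response to 9-cis RA also stays open: over the genes called with both compounds at 48 h, the ratio of the 24 h slope of a 9-cis RA sample to that of an ATRA sample ran from 1.02 to 1.131 (1.07 for the means), above 1 in every pair of samples. Both 9-cis RA 24 h samples are among the samples apart, so that group and term overlap, and a true part of the response may be removed with the term.

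20 genes, SERPINA3 and ECM1 among them, were lower with ATRA than with 9-cis RA over both times. With the samples apart as a term 0% of these 20 genes lost their call (median -0.74 before and -0.73 after), but the test could hardly have shown a loss. The samples apart are replicate 4 of ATRA at both times and both 9-cis RA samples at 24 h, so they weigh little on the mean of both times. At 24 h, where they weigh more, some calls between the isomers were lost with the term. Whether the expression difference that sets samples apart adds to these 20 calls stays open. The LXR targets had a median of -0.16 and a camera p of 0.0122 in this comparison, which met the limits set before the test. The list did not pass after adjustment (adjusted p = 0.0752, and 0.19 with an estimated correlation). Its member ABCA1 (-0.76 ± 0.12) is itself among the 20 genes. Members such as PLTP (0.26 ± 0.11), MYLIP (0.20 ± 0.10) and APOE (0.14 ± 0.12) went the other way. Activation of LXR target genes through RXR therefore stays open. For the PPAR targets camera's p was 0.071, above the 0.05 set before the test.

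For ATRA over both times 1 of 100 groupings of the samples gave as many genes, the real one (2890, against 14 at most in the others). For the isomers over both times it was also 1 of 100 (23, against 12 at most). A share of 0.01 is the smallest that 100 groupings allow, and it makes an accident of grouping unlikely among these samples. Regrouping cannot tell the treatment from a difference between cultures, since the labels do not say whether the samples came from separate cultures. For 9-cis RA over both times the 18 groupings are too few for a share under 0.05 (2524 in the real one, 1 of 18, against 1 at most in the others).

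A test of the difference between the times picked out the ATRA effect on MXD4 (1.238). It also picked out CYP26B1 (fitted value 2.07), which was detected on 1 of 3 EtOH arrays at 24 h, DCN (fitted value 1.715) and KCNJ13 (fitted values 1.359 with ATRA and 1.722 with 9-cis RA). DCN and KCNJ13 were not detected with EtOH, nor DCN with ATRA at 24 h, so that these fitted values rest on signals below detection and are no measured sizes.

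Probes with no single gene listed lie outside the comparisons of genes. Of 4075 such probes 70 passed for ATRA at 24 h, 265 for ATRA at 48 h, 200 for 9-cis RA at 24 h and 154 for 9-cis RA at 48 h.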

How the results depend on the processing

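The settings by array set and by samples apart were added after the data were seen, and the others were planned. Slides are not given by the files, so the planned fit by slide was not run. Of 7068 alternative values of named genes 6508 kept their call, 501 were weaker, 59 stronger and 0 reversed. Many of these genes were named for their large differences or low p in the same arrays, so a high share was likely beforehand. The share that kept the call was 62.8% with set 2 alone and 98.8% with no detection filter. A change of sign was counted as reversed only where at least 1 of the 2 fits passed. Values that changed sign without passing in either fit are among those that kept their call. Values below are the counts of passing genes and lists that moved by more than 1.5 times, and at the end the ranges over single samples left out. Counts of rises over 2-fold and list medians also moved with the scaling, mostly to smaller values without background correction. Only some of the list medians are given above. With 20 arrays as independent samples the counts were 1593 (ATRA 24 h), 3305 (9-cis RA 24 h), 1974 (9-cis RA 48 h), 138 and 15 (isomers at 24 and 48 h), 75 (isomers, both times), 23 and 428 (ATRA and 9-cis RA over time) and 43 (EtOH), and the lists 1 (9-cis RA 24 h), 10 (ATRA over time), 2 (EtOH) and 5 (isomers, both times). With the title number as a random block they were 11, 7 and 37 (isomers), 14 and 65 (over time) and 7 (EtOH). In fits of only the groups compared they were 583 (ATRA 48 h), 3927 and 248 (9-cis RA), 1 and 1 (isomers), 1 and 0 (over time, 1758 unadjusted for 9-cis RA) and 0 (EtOH, 321 unadjusted). Set 2 alone, with 1 array in each EtOH and 9-cis RA group, gave 87 and 101 (ATRA), 49 and 73 (9-cis RA), 396 and 225 (both times), 0, 0 and 1 (isomers), 0 and 0 (over time) and 0 (EtOH). Set 1 alone gave 363 and 1 (isomers), 98 (9-cis RA over time) and 0 (EtOH). The array set as a term gave 12 (isomers 24 h), 11 and 23 (over time) and 7 (EtOH), with lists at 1 (isomers 48 h), 2 (EtOH) and 6 (isomers, both times). The samples apart as a term gave 523 (9-cis RA 24 h), 3 and 44 (isomers 24 h, both times), 13 and 4 (over time), with lists at 10 (9-cis RA 24 h), 1 and 6 (isomers), and leaving them out gave 399 (ATRA 24 h), 1 (ATRA over time) and 0 (EtOH, 746 unadjusted). The submitters' values gave 4 and 7 (isomers), 8 (9-cis RA over time) and 5 (EtOH), with lists at 1 (9-cis RA 24 h), 10 (ATRA over time) and 5 (isomers, both times). Log2 with quantile normalization gave 7 (isomers 48 h), 4 (9-cis RA over time) and 7 (EtOH). Detection on all 20 arrays gave 2, 1 and 11 (isomers) and 1 and 5 (over time), all detected probes 3 and 13 (isomers 24 h, both times) and 1 (ATRA over time), and the trend with robust variances 3 (9-cis RA over time). An estimated correlation left 1 list in each of the 4 comparisons with EtOH and 0 for the isomers at 48 h and both times, ATRA over time and EtOH over time, 4 in total. By fry 20, 18 and 19 lists passed (ATRA 48 h, 9-cis RA 24 and 48 h), 3 and 7 for the isomers (24 h, both times), 1 and 4 over time and 70 in total. Leaving out 1 sample moved the counts between 211 and 1082 (ATRA 24 h), 816 and 3273 (ATRA 48 h), 301 and 2254 (9-cis RA 24 h), 442 and 2576 (9-cis RA 48 h), 1697 and 4008 (ATRA, both times), 1480 and 3633 (9-cis RA, both times), 1 and 12 (isomers 24 h), 4 and 40 (isomers, both times), 1 and 75 and 0 and 244 (ATRA and 9-cis RA over time) and 0 and 366 (EtOH), and the lists between 2 and 8 (ATRA 48 h), 1 and 4 (9-cis RA 24 h), 3 and 9 (9-cis RA 48 h), 0 and 7 (isomers 48 h), 1 and 7 (isomers, both times), 0 and 6 (ATRA over time), 0 and 2 (EtOH) and 13 and 28 in total. Where that left 1 sample in a group, it was assumed to vary like the other groups.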

Other observations

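The lists named here were fixed before the data were seen, and the single genes were chosen after their values were seen.

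Some single genes differed from EtOH with both isomers (values are log2 differences for ATRA at 24 and 48 h, then 9-cis RA at 24 and 48 h). HOXA2, a hindbrain patterning gene, was detected on every retinoid array and on 0 EtOH arrays (adjusted p of 0.00243 or less), and HOXB8 was higher by 0.79, 0.87, 0.95 and 0.92 (adjusted p of 0.00764 or less). The homeobox gene MSX1 was higher by 2.72, 2.72, 2.75 and 2.97, and the splicing regulator ESRP1 changed by -0.84 with ATRA and -1.03 with 9-cis RA at 24 h. The small leucine-rich proteoglycan LUM was 1.34 higher after 48 h of ATRA and 1.49 higher after 48 h of 9-cis RA, and CD68 was 1.03 and 1.39 higher. LUM, CD68 and ESRP1 come from lists of other cell types, and no source of such cells was tested.

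As lists, most gene programmes outside the retinoid, pigment and YAP groups did not pass in the comparisons with EtOH. The HOX genes gave camera adjusted p-values of 0.242, 0.355, 0.32 and 0.171. S phase and DNA replication gave 0.673, 0.252, 0.758 and 0.171, G2 and mitosis 0.531, 0.837, 0.578 and 0.917, and cell cycle inhibitors and p53 targets 0.467, 0.983, 0.802 and 0.36. The interferon-stimulated genes gave 0.083, 0.218, 0.0785 and 0.0609, and passed only for 9-cis RA averaged over both times, with 9 of 20 higher and 0 lower (adjusted p = 0.0253, and 0.196 with an estimated correlation). Neural crest and neuronal genes gave 0.0515, 0.412, 0.385 and 0.155.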
